A study of Rattus norvegicus with 64 samples.

How the data were processed

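RNA sequencing was run on lung tissue of male Sprague-Dawley rats, an outbred laboratory strain, that had breathed either filtered air or dust of fracking sand, the mainly silica sand pumped into wells during hydraulic fracturing. Exposure took place in a whole-body chamber for 6 hours a day on 4 days, at 10 or 30 mg/m3, and lungs were taken 1, 7 or 27 days after the last exposure. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a kit that keeps strand information. Each dose was a study of its own with its own air-breathing rats, so the 64 libraries fall into 12 groups. The 10 mg/m3 study holds 28 libraries, with 5 air and 5 dust rats at day 1, 5 and 5 at day 7, and 4 and 4 at day 27. The 30 mg/m3 study holds 36 libraries, 6 in each of its 6 groups. Every library carries a number of its own in its title, taken here as the number of the rat, so each library stands for 1 animal and no library is shared between comparisons of the 2 doses.

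The deposited values are whole-number counts of reads per gene symbol, 1 column per library and 1 table per dose, with no normalisation by the authors. Per the submitters' processing notes, the tools were bcl2fastq 2.19, Trimmomatic 0.35, HISAT2 2.1.0, SAMtools 1.8 and HTSeq 0.6.1, with the rat genome build Rnor_6.0. The gene annotation and the strand setting of the counting step are not given in the sources used here, so overlapping and antisense genes are uncertain. Genes that share reads with a near-identical copy can lose reads at the counting step. Symbols ending in -2 were read as second copies of a locus, which the sources used here do not state; if so, their values and those of their partner are uncertain for that reason. Both tables list the same 30045 symbols, of which 3625 had 0 counts in every library, and every column was assigned to a sample. A RefSeq table of another rat assembly, GRCr8, was used only to look up names; 19073 symbols were found there by symbol, and no coordinates are given because the builds differ.

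Library totals ran from 3420235 to 12359518 counts. In every group, each pair of libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 2.074. So no column is a copy of another of its own group, and pairs from different groups were not compared. That the libraries are separate rats rests on the titles alone. The fits gave a common biological coefficient of variation of 16.11% in the 10 mg/m3 study and 16.74% in the 30 mg/m3 study.

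Counts were tested in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM factors, genes with low counts were removed by filterByExpr with its minimum count of 10 and minimum total count of 15, and each contrast was tested with the quasi-likelihood F test with robust estimation and Benjamini-Hochberg adjustment at 0.05. The 6 groups of a study entered 1 fit, which left 15668 genes at 10 mg/m3 and 15551 genes at 30 mg/m3. Dust was compared with air of the same study and day, the mean of the 3 daily effects was tested, and a test on 2 degrees of freedom asked whether the effect depended on the day. The doses were compared only as a difference of within-study effects, in 1 fit of all 64 libraries with 16190 genes. Air groups of day 27 and day 1 were compared to show the change over time without dust. Levels are given as CPM scaled by the TMM factors, as mean ± SD over rats, and log2 fold changes with their standard errors (SE). The lowest and highest levels of Myh6 and the levels of Alb in CPM were scaled by the library total alone, without these factors.

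A total of 39 lists of genes of pathways and cell types, including cell types that a piece of lung could carry along, were fixed before the data were examined. Of these, 38 had at least 5 genes tested; the mitochondrially encoded protein genes are not in the tables used here. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with fry, and with an exact two-sided permutation test of list means; Benjamini-Hochberg adjustment ran over the 38 lists. The genes named in the text follow a rule also fixed before the data were examined: a panel of 8 genes (Ccl2, Cxcl1, Il1b, Hmox1, Spp1, Mmp12, Lcn2 and Sftpc) for each dust comparison, the 8 largest rises and 8 largest falls among genes past the threshold with a symbol and a mean of at least 1 CPM, up to 3 members of each fixed list, and, where fewer than 10 genes passed, the 3 smallest unadjusted p in each direction, given as values that did not pass. For mean effects and differences between doses, the 5 largest rises and falls are named. For air over time these are the 5 largest, by the mean of both studies, among genes past the threshold in the same direction in both; members of the fixed lists serve as further examples.

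The procedure was tested on simulated data drawn from the real means and library sizes, with 200 changed genes. For dust against air at day 1, 73.1% of 2-fold changes were recovered at 10 mg/m3 (15668 genes) and 80.6% at 30 mg/m3 (15551 genes); 1.5-fold changes were recovered in 47.8% and 76.1%. False calls made up 5.3% and 5.06% of the calls in these 2 comparisons, and between 2.53% and 8.14% over the 6 dust comparisons, the highest at 30 mg/m3 on day 7 (14 of 172). The simulation drew each gene independently, with no structure shared among genes or libraries. These rates therefore need not hold for the real libraries. Alternatives fixed before the data were examined were median-of-ratios size factors, no filter, a filter at 1 CPM, no robust estimation, DESeq2 1.42.0, limma voom with quality weights, the first surrogate variable from sva 3.50.0, only the compared groups in the fit, a minimum fold of 1.5, leaving out libraries more than 4 scaled MAD below the median correlation (1 library, dust rat 27 of day 1 at 10 mg/m3), and leaving out each library in turn. Alternatives chosen after seeing the data were a cardiac score as a covariate, the share of counts on the mitochondrial ribosomal RNA genes Rnr1 and Rnr2 as a covariate, leaving out libraries above 100 CPM of the liver transcript Alb, and leaving out libraries with a count for over 21000 genes.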

Results

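Total RNA was sequenced from the lungs of 64 rats, 28 in a study of 10 mg/m3 fracking sand dust and 36 in a study of 30 mg/m3. Each study held air and dust groups at 1, 7 and 27 days after 4 days of exposure, with 5, 5 and 4 rats per group at 10 mg/m3 and 6 rats per group at 30 mg/m3. The surfactant gene Sftpc, a marker of alveolar type 2 cells, was among the abundant transcripts, at 9460 ± 1610 CPM (SD, n = 5) in air at day 1 of the 10 mg/m3 study and 10950 ± 1800 CPM (SD, n = 6) in that of the 30 mg/m3 study. Library totals ran from 3420235 to 12359518 counts. The lowest total belonged to dust rat 27 of day 1 at 10 mg/m3; the next lowest library of that group held 9255890 counts.

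**Figure D1:**
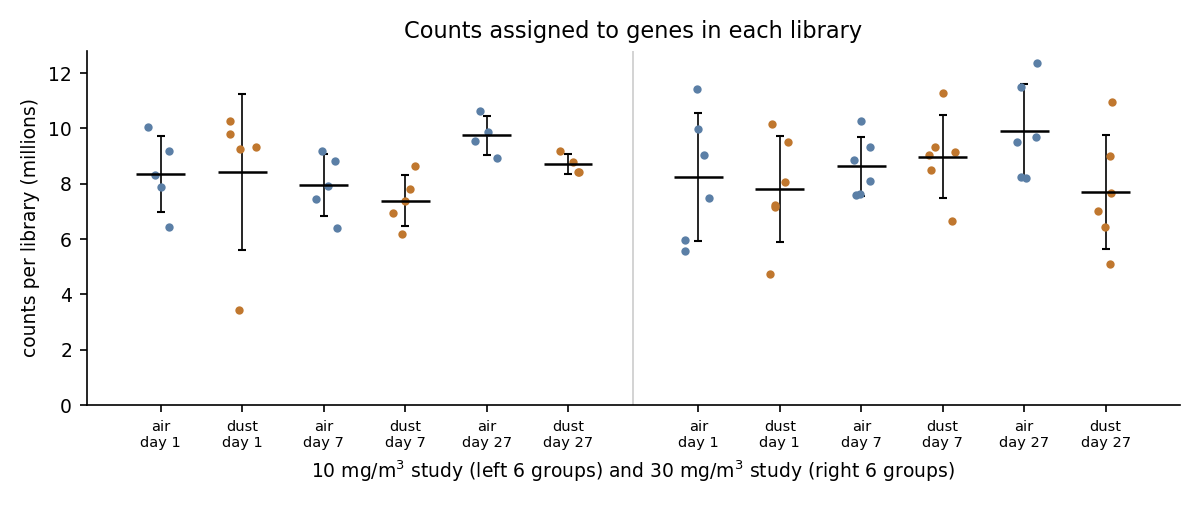
Total counts per library (vertical axis, M counts) for the 12 groups, the 10 mg/m3 study on the left and the 30 mg/m3 study on the right; blue points are air, orange points dust, lines are means and bars the SD. Totals lie between 3.42 and 12.36 M counts, and the lowest is a dust library of day 1 at 10 mg/m3.

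The comparison of dust with air at 10 mg/m3 on day 1 asks for the early response to the lower dose. The genes that passed were led by parts of the circadian clock. A score of clock genes also rose with the number in the title within groups (mean Spearman's rho of 0.785). In each comparison the dust rats carried the higher numbers, so these changes need not be due to dust. Dbp, a transcription factor driven by the clock, rose from 5.8 ± 1.9 to 30.7 ± 12.8 CPM (SD, n = 5 each), a log2 fold change of 2.41 ± 0.45 (SE; adjusted p = 0.0388). Arntl, the clock's central activator, fell from 73.1 ± 6.24 to 38.8 ± 4.90 CPM, a log2 fold change of -0.92 ± 0.14 (SE; adjusted p = 0.00363). Tef, a relative of Dbp, rose by 0.63, and the clock repressors Bhlhe41 and Bhlhe40 rose by 0.81 and 0.48 on the log2 scale.

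Among the 17 circadian genes tested, 4 rose and 1 fell over all genes, and 9 rose and 5 fell when adjusted over the list alone. Members that passed only over the list alone include Nr1d1, a repressor of Arntl, with a log2 fold change of 2.62, and Cry1 with -0.70. Members moved both ways, and camera did not call the list as a whole (adjusted p = 0.0702; 0.852 with an estimated correlation). Outside the clock, Muc1, a membrane mucin of the airway and alveolar surface, rose from 92.1 ± 21 to 142 ± 20.7 CPM, and Cited2, a transcriptional co-regulator, rose by 0.71 on the log2 scale. The kinase Tlk1 rose by 0.96, the sulfotransferase Chst1 by 0.73 and the tetraspanin Tspan15 by 0.55. Itgae, the integrin chain that anchors lymphocytes in epithelium, fell by 0.80, Cnksr2 by 0.59 and St7l by 0.54 on the log2 scale.

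Alveolar type 2 and surfactant genes were higher as a list on day 1 at 10 mg/m3, with 16 of 19 members above 0 and a median log2 difference of 0.181 (camera adjusted p = 9.4e-05; adjusted p = 0.884 with an estimated correlation). Over all genes 1 member rose, and 7 rose when adjusted over the list alone, among them Napsa, a protease that processes surfactant proteins, at 0.50. Immediate early genes were higher in 19 of 22 members (camera adjusted p = 8.08e-06; adjusted p = 0.884 with an estimated correlation); none passed over all genes and 7 rose when adjusted over the list alone, such as Egr2 at 0.78. Alveolar type 1 markers were higher in 16 of 17 members (camera adjusted p = 0.00566; adjusted p = 0.915 with an estimated correlation), with 0 members past the threshold over all genes and 1, Cldn18, adjusted over the list alone. None of the 8 panel genes passed: the log2 fold change was 0.99 for Lcn2, an iron-binding protein of innate defence (adjusted p = 0.171), 0.43 for the neutrophil chemokine Cxcl1 (adjusted p = 0.458) and -0.32 for the monocyte chemokine Ccl2.

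In all, 20 of 15668 genes passed on day 1 at 10 mg/m3 by edgeR, 12 higher and 8 lower, where DESeq2 called 473 and limma voom 520. With only the compared groups in the fit 3 genes passed. The count moved widely with single rats: it was 1147 without air rat 21, whose library had 3.01% of its counts on mitochondrial ribosomal RNA, and 1 without air rat 17. With the mitochondrial ribosomal RNA share as a covariate, an alternative chosen after seeing the data, 0 genes passed.

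**Figure D2:**
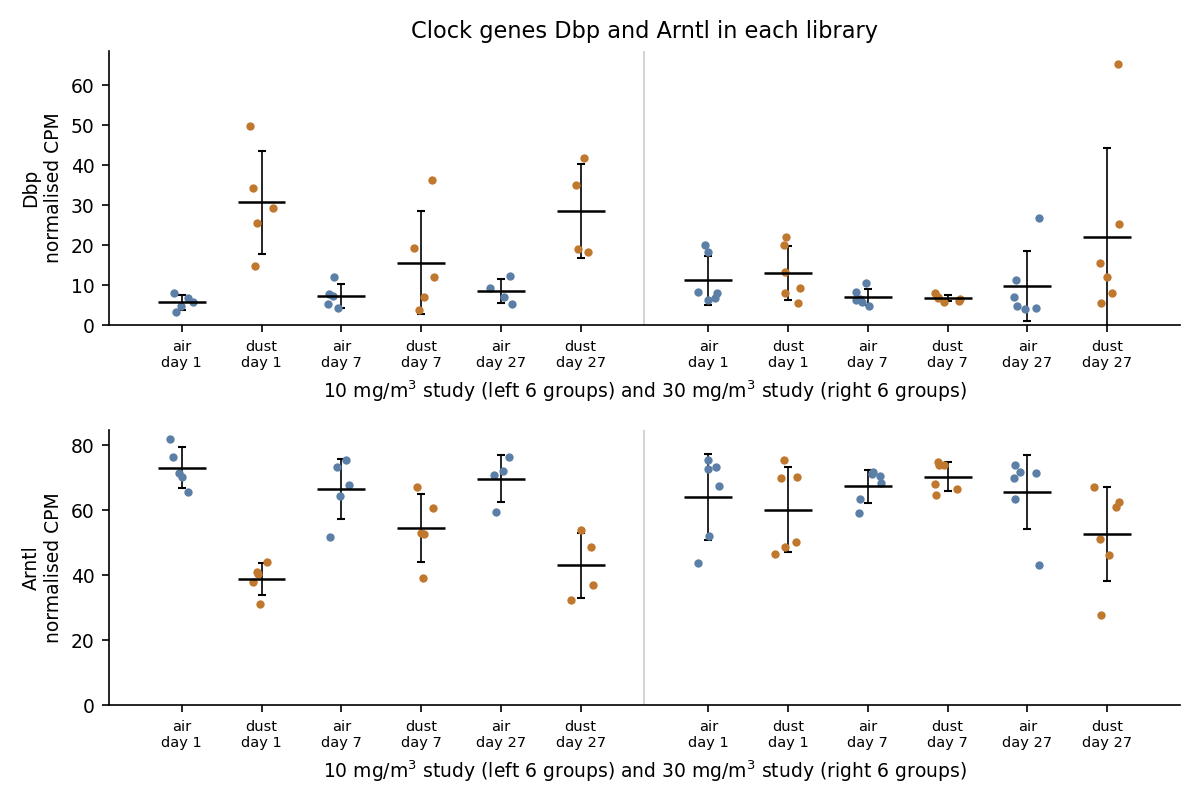
Levels of the clock genes Dbp and Arntl in every library (vertical axes, CPM), groups ordered by day with the 10 mg/m3 study on the left and the 30 mg/m3 study on the right; blue points are air, orange points dust, lines are means and bars the SD. At day 1 of the 10 mg/m3 study Dbp averages 5.8 CPM in air and 30.7 CPM in dust, and Arntl 73.1 and 38.8 CPM.

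At 10 mg/m3 on day 7, no gene passed. Cardiac muscle markers, which in rat lung mark the sleeve of heart muscle around the pulmonary veins, were higher as a list, with 16 of 16 members above 0 and a median log2 difference of 1.51 (camera adjusted p = 7.53e-09). The spread within groups was wide: the heart myosin gene Myh6 ran from 0 to 285 CPM in air and from 8.09 to 423 CPM in dust. T cell markers were higher (camera adjusted p = 7.63e-05), as were ciliated cell markers (0.000113), secretory airway genes (0.00242), neutrophil markers (0.00252), collagen and matrix genes (0.0043) and smooth muscle markers (0.00556). Mesothelial markers were lower, with a median of -0.604 (camera adjusted p = 0.000723), and so were mast cell and basophil markers (0.0354). None of these 9 calls held, each having adjusted p = 0.552 with an estimated correlation, and 0 members of any passed over all genes or adjusted over the list alone.

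Some of the genes with the smallest p on day 7 at 10 mg/m3 are given here as values that did not pass (adjusted p = 0.996 each). The log2 fold change was 1.00 ± 0.26 (SE, n = 5 per group) for Oas1k of the oligoadenylate synthetase family and 1.23 for LOC691418. It was -0.36 for the scaffold gene Dlg3, -1.19 for the drug efflux pump Abcb1b and -2.10 for LOC100359752. Panel genes also stayed short of the threshold, with 0.11 for Cxcl1, 0.48 for Lcn2 and -0.57 for Ccl2. By edgeR 0 of 15668 genes passed and 620 had an unadjusted p under 0.05; DESeq2 and limma voom both called 0.

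On day 27 at 10 mg/m3 no gene passed either. Arntl again had a negative value, -0.70 ± 0.15 (SE, n = 4 per group; adjusted p = 0.542), and Dbp and the clock gene Per3 had log2 fold changes of 1.74 and 1.10. When adjusted over the list alone, 7 circadian genes rose and 3 fell (camera adjusted p = 0.44; adjusted p = 0.713 with an estimated correlation). Heat shock genes were lower in 17 of 17 members, with a median of -0.284 (camera adjusted p = 3.1e-09; adjusted p = 0.393 with an estimated correlation). Erythroid genes (camera adjusted p = 0.00153), cholesterol synthesis genes (0.0135), alveolar type 1 markers (0.014), alveolar type 2 genes (0.014), T cell markers (0.0176), macrophage activation genes (0.0235) and alveolar macrophage markers (0.0268) were lower, each with adjusted p = 0.713 with an estimated correlation.

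The other lists called on day 27 at 10 mg/m3 were also lost in that second test. Glucocorticoid response genes were lower (camera adjusted p = 0.00389; adjusted p = 0.649 with an estimated correlation), as were adipose markers (0.0134; adjusted p = 0.393 with an estimated correlation) and ribosomal protein genes (0.0268; adjusted p = 0.913 with an estimated correlation). Smooth muscle markers (0.00793) and B cell markers (0.0332) were higher, with adjusted p = 0.713 with an estimated correlation for both, and so were proliferation genes (0.0279; adjusted p = 0.776 with an estimated correlation). Apart from the circadian list, 0 members of these lists passed when adjusted over the list alone.

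Other values with a small p on day 27 at 10 mg/m3 were 1.42 for the protocadherin Pcdhb5 and -0.62 for Ptprr-2, whose symbol was read as a second copy of a phosphatase locus. LOC102553715 had -5.16, where air averaged 33.4 ± 63.9 CPM because of a single air library. Among panel genes Spp1, the matrix and macrophage protein osteopontin, had 1.05 ± 0.60 (SE; adjusted p = 1). By edgeR 0 genes passed and 369 had an unadjusted p under 0.05; DESeq2 and limma voom both called 0.

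Averaged over the 3 days at 10 mg/m3, all 5 genes that passed were clock genes, for which the higher title numbers of the dust rats are a limit here too. Dbp rose by 1.75 ± 0.26 on the log2 scale (SE; adjusted p = 0.00578), the nuclear receptor gene Nr1d2 by 1.05 ± 0.18 (adjusted p = 0.0222) and Tef by 0.45 ± 0.08. The core activator Arntl fell by 0.63 ± 0.08 (adjusted p = 0.000222) and the repressor Cry1 fell by 0.68 ± 0.13 (adjusted p = 0.0266). Over the circadian list alone, 9 genes rose and 6 fell (camera adjusted p = 0.0151; adjusted p = 0.306 with an estimated correlation).

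For the mean effect at 10 mg/m3, 3 of the 5 genes rose and 2 fell, where DESeq2 called 21 genes and limma voom 36. The count was 2 with a surrogate variable, and leaving out 1 library gave from 2 to 20. It was 2 with the cardiac score, 2 without libraries above 100 CPM of Alb and 3 with the mitochondrial ribosomal RNA share, all alternatives chosen after seeing the data. The lists were tested for this effect only after the data had been seen. Secretory airway genes (camera adjusted p = 0.00615), ciliated cell markers (0.0149), immediate early genes (0.0216), collagen genes (0.0229) and integrated stress response genes (0.0403) were higher, and heat shock genes (0.00615) and erythroid genes (0.0403) lower, each with adjusted p = 0.821 with an estimated correlation. Adjusted over the list alone, 1 integrated stress response gene rose and 1 heat shock gene fell, and 0 members of the other lists passed. No gene had an effect that depended on the day by edgeR, with 1141 at an unadjusted p under 0.05; DESeq2 called 0 and limma voom 1.

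At 30 mg/m3 on day 1, Cxcl1 and Lcn2 had higher values with dust, but no gene passed. Cxcl1 averaged 9.69 ± 5.21 CPM in air and 19.9 ± 6.46 CPM in dust (SD, n = 6 each), a log2 fold change of 1.06 ± 0.27 (SE; adjusted p = 0.163). Lcn2 averaged 75.9 ± 39.6 and 159 ± 54.3 CPM, a log2 fold change of 1.08 ± 0.31 (adjusted p = 0.182), and the macrophage elastase Mmp12 had 0.67 (adjusted p = 0.226). Nfkbiz, a regulator of NF-kB target genes, had 0.55, the DNA primase gene Prim1 1.10, and Aoc1, which degrades histamine, 1.38. Sirpa, an inhibitory receptor of macrophages, had -0.46, the mitochondrial receptor Nlrx1 -0.45 and Bean1 -0.36, all with adjusted p = 0.161.

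By list, the chemokine and cytokine genes were not called on day 1 at 30 mg/m3 (camera adjusted p = 0.0813; adjusted p = 0.836 with an estimated correlation), with 0 members past the threshold over all genes and 1, Cxcl1, adjusted over the list alone. Alveolar type 1 markers were lower in 17 of 17 members, with a median of -0.175 (camera adjusted p = 9.86e-06; adjusted p = 0.586 with an estimated correlation); 3 fell when adjusted over the list alone, Rtkn2, the water channel gene Aqp5 and Akap5. Proliferation genes were higher in 25 of 27 members, with a median of 0.274 (camera adjusted p = 0.000292; adjusted p = 0.836 with an estimated correlation); 1 rose when adjusted over the list alone, the mitotic gene Cdc20. Ribosomal protein genes (camera adjusted p = 0.00501), ciliated cell markers (0.0211) and cholesterol synthesis genes (0.0414) were higher, and collagen genes (0.00584), heat shock genes (0.021) and immediate early genes (0.0211) lower. These 6 had adjusted p = 0.836 with an estimated correlation and 0 members past the threshold adjusted over the list alone.

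By edgeR 0 of 15551 genes passed on day 1 at 30 mg/m3, and DESeq2 called 37 and limma voom 0. By edgeR 2334 genes had an unadjusted p under 0.05, where 778 would be the number for independent genes without any effect. That excess is not set apart from chance. In a fit of these 2 groups alone, 17 of 100 splits of the libraries had at least as many as the real one (1373 genes, highest other 3807). Without air rats 51 and 53, whose libraries had counts for 21889 or more genes, 877 genes passed, 425 higher and 452 lower, among them Cxcl1 (adjusted p = 0.0435), Aoc1 (0.00863), Nfkbiz (0.00863) and Sirpa (0.00391), but not Lcn2 (0.0585); this alternative was chosen after seeing the data. What sets these 2 libraries apart is not known, and whether genomic DNA or another library was mixed in was not tested, so the air levels of that group are uncertain.

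**Figure D3:**
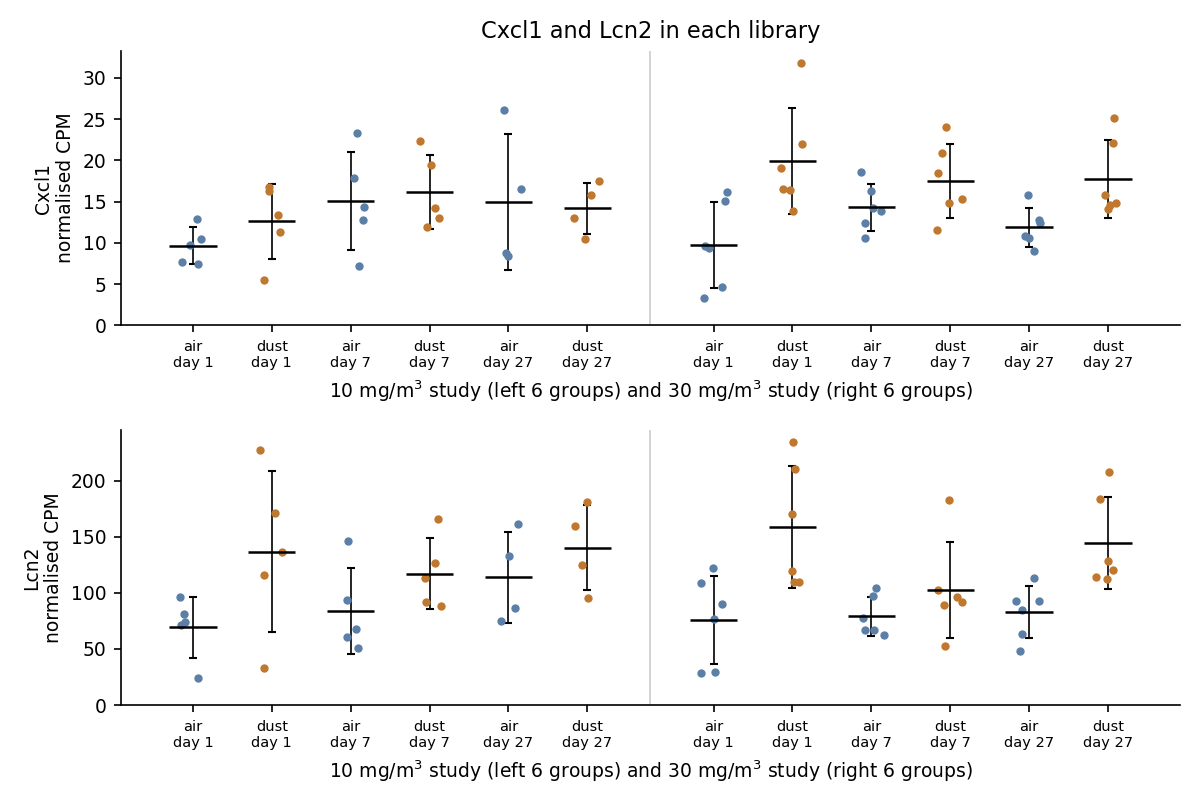
Levels of Cxcl1 and Lcn2 in every library (vertical axes, CPM), groups ordered by day with the 10 mg/m3 study on the left and the 30 mg/m3 study on the right; blue points are air, orange points dust, lines are means and bars the SD. At day 1 of the 30 mg/m3 study Cxcl1 averages 9.69 CPM in air and 19.9 CPM in dust, and Lcn2 75.9 and 159 CPM, with overlap of single rats.

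At 30 mg/m3 on day 7, genes of striated muscle fell. Ryr2, the calcium release channel of heart muscle, fell from 46.6 ± 21.5 to 8.22 ± 3.03 CPM (SD, n = 6 each), a log2 fold change of -2.50 ± 0.49 (SE; adjusted p = 0.0359). Ttn, the giant spring protein of the sarcomere, fell from 411 ± 209 to 96.8 ± 30.7 CPM (adjusted p = 0.0437). The Z-disc gene Ldb3 fell by 1.22, Fndc5, which encodes the irisin precursor, by 1.60 and Txlnb by 2.48 on the log2 scale. Pygm, the muscle glycogen phosphorylase, fell by 0.63 and the proteoglycan gene Gpc1 by 0.96.

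Cardiac muscle markers were lower in 18 of 18 members on day 7 at 30 mg/m3, with a median of -2.39 (camera adjusted p = 4e-36), and this list kept its call with an estimated correlation (adjusted p = 0.0126) and by fry (adjusted p = 0.0157). Over all genes 1 member fell, and 17 fell when adjusted over the list alone, such as Hspb7 at -1.74, the myosin heavy chain Myh6 at -2.71 and the troponins Tnni3 at -2.58 and Tnnt2 at -2.18. The exact two-sided permutation test of the list mean gave p = 0.00216, the smallest that 6 against 6 rats allow, and 0.0823 after adjustment over the 38 lists. The myosin light chain Myl3 averaged 15.3 ± 18.7 CPM in air and 0.0936 ± 0.0498 CPM in dust. The share of counts on mitochondrial ribosomal RNA was lower with dust too, 0.678 ± 0.157% in air and 0.256 ± 0.14% in dust (exact permutation p = 0.00216, adjusted p = 0.013, two-sided). The liver transcript Alb ran from 15.6 to 368 CPM in air and from 7.09 to 12.7 CPM in dust.

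Glucocorticoid response genes were lower on day 7 at 30 mg/m3, with a median of -0.186 (camera adjusted p = 9.17e-06; adjusted p = 0.258 with an estimated correlation); 0 passed over all genes and 5 fell when adjusted over the list alone, led by Ddit4, an inhibitor of mTOR signalling, at -1.13, and Nfkbia, the inhibitor of NF-kB, at -0.59. The mean log2 CPM of the glucocorticoid list was 5.734, 5.704 and 5.477 in air rats 65, 66 and 71. In air rats 68, 69 and 70 it was 5.057, 5.075 and 5.036, within the dust range of 4.849 to 5.434. The difference thus came from part of the air group. Erythroid genes were lower in 13 of 13 members, with a median of -1.27 (camera adjusted p = 0.000163), and interferon response genes higher with a median of 0.204 (camera adjusted p = 7.61e-05), both with adjusted p = 0.597 with an estimated correlation and 0 members adjusted over the list alone. Secretory airway genes (0.013), smooth muscle markers (0.0147), heat shock genes (0.02) and immediate early genes (0.00567) were lower, each with adjusted p = 0.597 with an estimated correlation. Adjusted over the list alone, 1 secretory airway gene fell, and 0 members of the other 3 lists passed. Proliferation genes (0.0106; adjusted p = 0.651 with an estimated correlation) and mast cell markers (0.0468; adjusted p = 0.646 with an estimated correlation) were higher, with 0 and 1 members risen adjusted over the list alone. None of the 8 panel genes passed, with 0.29 for Cxcl1, 0.37 for Lcn2 and 0.27 for the haem oxygenase gene Hmox1.

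By edgeR 10 of 15551 genes passed on day 7 at 30 mg/m3, all lower, where DESeq2 called 55 and limma voom 21; the 2 not named by the rule are Ldhb and LOC103691832. The count was 0 with a cardiac score and 0 with the mitochondrial ribosomal RNA share as a covariate, both alternatives chosen after seeing the data, and it was 0 without air rat 70, without dust rat 76 or without dust rat 79.

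**Figure D4:**
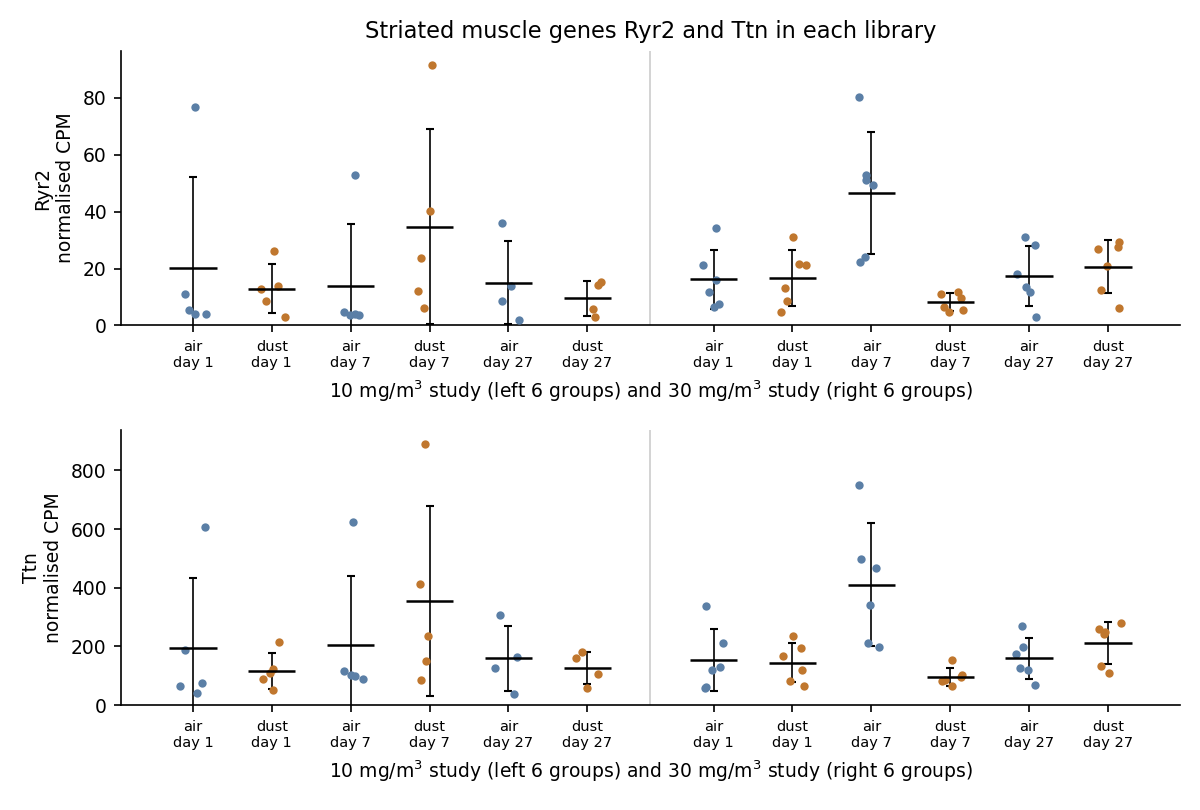
Levels of the muscle genes Ryr2 and Ttn in every library (vertical axes, CPM), groups ordered by day with the 10 mg/m3 study on the left and the 30 mg/m3 study on the right; blue points are air, orange points dust, lines are means and bars the SD. At day 7 of the 30 mg/m3 study Ryr2 averages 46.6 CPM in air and 8.22 CPM in dust, and Ttn 411 and 96.8 CPM.

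On day 27 at 30 mg/m3 no gene passed. Ciliated cell markers were lower in 20 of 20 members, with a median of -0.32 (camera adjusted p = 4.51e-08; adjusted p = 0.703 with an estimated correlation), and cholesterol synthesis genes were lower in 20 of 22, with a median of -0.165 (3.52e-06; adjusted p = 0.703 with an estimated correlation). Xenobiotic metabolism genes were lower (5.84e-05; adjusted p = 0.584 with an estimated correlation), and 2 cytochrome P450 genes, Cyp2s1 at -0.48 and Cyp4b1 at -0.26, fell when adjusted over the list alone. Heat shock genes were lower (5.78e-05; adjusted p = 0.665 with an estimated correlation). Ribosomal protein genes (0.00713), mesothelial markers (0.0184), alveolar type 2 genes (0.0184) and endothelial markers (0.047) were lower and proliferation genes (0.00398), T cell markers (0.0289) and interferon response genes (0.047) higher, each with adjusted p = 0.703 with an estimated correlation. The ribosomal list had a median of -0.0623 but a mean of 0.0485, and apart from the xenobiotic list 0 members of these lists passed adjusted over the list alone.

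Among values that did not pass on day 27 at 30 mg/m3, Slc12a8, a membrane transporter gene, had a log2 fold change of -0.93 ± 0.21 (SE, n = 6 per group; adjusted p = 0.232), Papss2, which makes the sulfate donor, -0.35 and the peptide transporter Slc15a2 -0.38. The RNA methyltransferase gene Nsun6 had 0.62, LOC103691241 1.18 and LOC103690957 1.13, each with adjusted p = 0.232. Panel genes had 0.81 for Lcn2 (adjusted p = 0.534), 0.57 for Cxcl1 (0.622), 0.56 for Mmp12 (0.571) and 1.05 for Spp1 (0.693). Spp1 averaged 4.84 ± 1.53 CPM in air and 9.90 ± 11.9 CPM in dust (SD, n = 6 each), so its SD in dust exceeded its mean. By edgeR 0 genes passed and 1141 had an unadjusted p under 0.05; DESeq2 called 0 and limma voom 45.

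Averaged over the 3 days at 30 mg/m3, the genes that rose include Lcn2, Cxcl1 and Cd177. Lcn2 rose by 0.75 ± 0.18 (SE; adjusted p = 0.0354) and Cxcl1 by 0.64 ± 0.15 (adjusted p = 0.0321) on the log2 scale. Cd177, a surface protein of neutrophils, rose by 1.05 ± 0.27 (adjusted p = 0.048), Aoc1 by 0.97 ± 0.17 (adjusted p = 0.0128) and the serine protease gene Tmprss4 by 0.80 ± 0.18 (adjusted p = 0.0278). Mmp12 rose by 0.56 (adjusted p = 0.0375), and so did Arg1, an enzyme of alternatively activated macrophages, by 0.36 (adjusted p = 0.0288). Other genes of these kinds went the other way, with -0.23 for Tnfaip2 of the NF-kB list (adjusted p = 0.0482) and -0.29 for Sirpa (adjusted p = 0.022). Rises with a smaller p than those of Lcn2 and Cxcl1 include the RNA-binding genes Hnrnpdl at 0.22 (adjusted p = 0.0173) and Pspc1 at 0.25 (adjusted p = 0.0218). Muscle genes fell, with -3.31 ± 0.76 for Myl3 (adjusted p = 0.0304), -0.73 for the sarcomere gene Mypn and -0.43 for Pygm. These mean effects do not show a fall on each day. A cardiac score, the mean log2 CPM of Myh6, Myl7, Actc1, Tnnt2, Tnni3 and Mybpc3, differed most on day 7. It averaged 4.25 in air and 3.94 in dust on day 1, and 5.73 and 3.64 on day 7. On day 27 it was 4.06 in air and 4.54 in dust. Gpc1 fell by 0.43, and Rnr1, the small ribosomal RNA of mitochondria, by 1.26 (adjusted p = 0.048).

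By list, proliferation genes were higher in 26 of 27 members for the mean effect at 30 mg/m3 (camera adjusted p = 6.94e-06; adjusted p = 0.613 with an estimated correlation), with 0 past the threshold over all genes and 5 risen adjusted over the list alone. Heat shock genes (3.29e-05) and alveolar type 1 markers (3.53e-05) were lower, both with adjusted p = 0.534 with an estimated correlation and both with 5 members fallen adjusted over the list alone. Cardiac markers were lower (5.35e-07; adjusted p = 0.613 with an estimated correlation), with 1 member fallen over all genes and 3 adjusted over the list alone. Immediate early genes (0.000708; adjusted p = 0.613 with an estimated correlation), collagen genes (0.00948) and fibrosis signalling genes (0.0185) were lower, the last 2 with adjusted p = 0.756 with an estimated correlation. Adjusted over the list alone, 2 fibrosis signalling genes fell, and 0 members of the other 2 lists passed. Neutrophil markers and the chemokine and cytokine genes were not among the 7 lists that camera called, although Cd177 and Cxcl1 rose. The lists were tested for this effect only after the data had been seen.

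For the mean effect at 30 mg/m3, 187 genes passed, 155 higher and 32 lower; DESeq2 called 417 and limma voom 1047. The count was 1 with the mitochondrial ribosomal RNA share as a covariate, 0 without the 5 libraries of this study above 100 CPM of the liver transcript Alb, and 1014 without the libraries with counts for over 21000 genes, all alternatives chosen after seeing the data. Leaving out 1 library gave from 22, without dust rat 79 of day 7, to 610, without air rat 53 of day 1. No gene had an effect that depended on the day at 30 mg/m3 by edgeR, with 688 at an unadjusted p under 0.05, while DESeq2 called 46 and limma voom 0.

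The doses were compared as a difference of dust effects. On day 1, Dbp differed by -2.23 ± 0.69 on the log2 scale (SE; adjusted p = 0.0322), with a dust effect of 2.41 at 10 mg/m3 and 0.17 at 30 mg/m3. Hsd17b13, a lipid droplet enzyme of liver, differed by 2.52 ± 0.46 (adjusted p = 0.00241), with -1.45 at 10 mg/m3 and 1.05 at 30 mg/m3, and the acute phase gene Crp by 2.88 (adjusted p = 0.0454), with -0.96 and 1.90. On day 1 at 30 mg/m3, the liver transcript Alb ran from 9.62 to 46.2 CPM in air and from 23.6 to 164 CPM in dust. Lpo, which encodes lactoperoxidase, differed by -4.24, the lymphocyte recombinase gene Rag1 by -3.08, the transcription factor Pitx1 by -2.58 and the class II chaperone gene RT1-DMb by -2.30. Ccdc183 differed by 2.09, Gtf2a1l by 1.93 and Ogn-2, read as a second copy of a locus, by 3.95; of the day 1 group means of Crp, Lpo and Rag1, the highest was 2.16 CPM, for Rag1 in air of the 30 mg/m3 study.

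In total 1678 of 16190 genes differed between the doses on day 1, 954 with the higher effect at 30 mg/m3 and 724 with the lower; DESeq2 called 1972 and limma voom 1292. With only the compared groups in the fit 6 genes passed, and leaving out 1 library gave from 452, without air rat 17 at 10 mg/m3, to 2825, without air rat 53 at 30 mg/m3. On days 7 and 27 edgeR called 0, with 1298 and 283 genes at an unadjusted p under 0.05; DESeq2 called 14 and 0, and limma voom 213 and 0. On no day did edgeR call genes at both doses, so a shared call was not possible. Across 15323 genes, which are not independent replicates, the dust effects at the doses had Pearson's r of -0.30 on day 1, -0.313 on day 7 and 0.194 on day 27, and the sign was the same for 32.5%, 38% and 63.5% of genes. The share of mitochondrial ribosomal RNA had log2 differences of dust and air on day 1 of 1.66 at 10 mg/m3 (exact permutation p = 0.119) and -0.65 at 30 mg/m3 (exact permutation p = 0.238), neither of which passed, and with that share as a covariate, an alternative chosen after seeing the data, 97 genes differed.

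**Figure D5:**
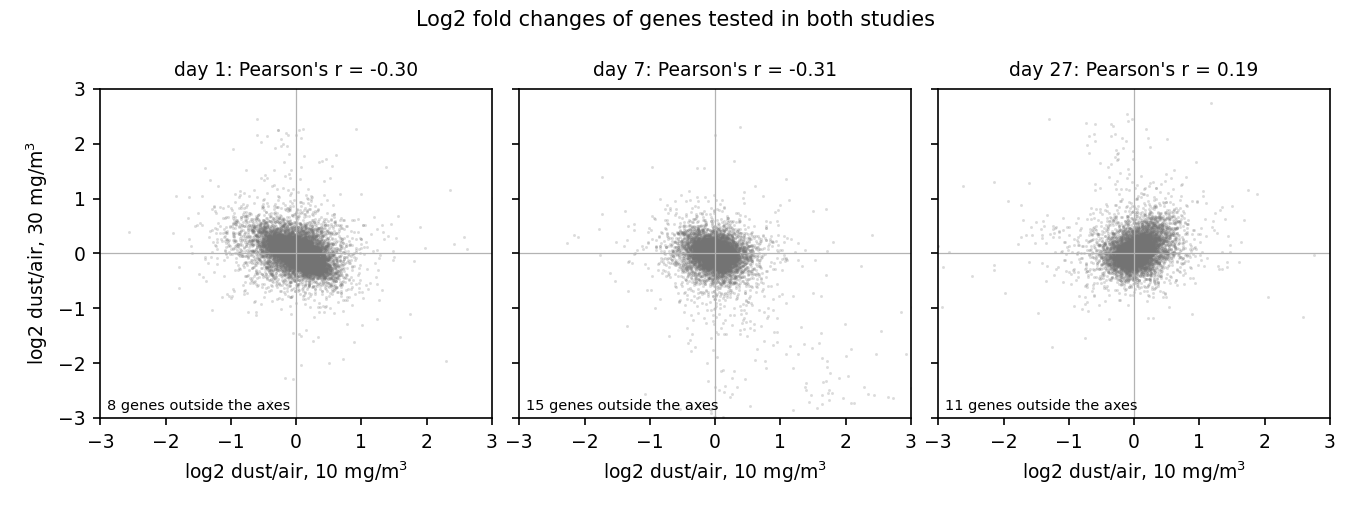
Log2 fold change of dust against air at 10 mg/m3 (horizontal axis) and at 30 mg/m3 (vertical axis) for 15323 genes at days 1, 7 and 27, 1 point per gene; 8, 15 and 11 genes lie outside the axes. Pearson's r across genes is -0.30, -0.313 and 0.194.

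In rats that breathed air, the comparison of day 27 with day 1 gives the background without dust. The genes named here were picked among those past the threshold in the same direction in both studies, so their agreement is set by that choice. Genes of cell division among them were Fam64a, active in mitosis, with log2 fold changes of -1.76 at 10 mg/m3 and -1.85 at 30 mg/m3, Sgol2, which protects centromeres, with -0.88 and -1.32, and the kinetochore gene Knstrn with -1.13 and -1.01 (adjusted p = 0.042 or less in each). The histone gene Hist1h2bl fell by 1.36 and 0.91 on the log2 scale and the protease inhibitor Pi15 by 1.23 and 0.98. Dmbt1, a secreted protein of mucosal defence, rose from 7.58 ± 4.17 to 20.1 ± 2.48 CPM (SD, n = 5 and 4) and from 8.57 ± 1.39 to 22.0 ± 7.94 CPM (SD, n = 6 and 6), and Dmbt1-2, read as its second copy, rose by 1.31 and 1.37 on the log2 scale. Cyb561d1 rose by 1.34 and 1.00, the prefoldin gene Pfdn2 by 1.14 and 0.82 and the lipid kinase gene Pi4k2a by 0.95 and 0.83.

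By list, proliferation genes were lower with time in air in 25 of 27 members at 10 mg/m3 (camera adjusted p = 2.29e-07; adjusted p = 0.613 with an estimated correlation) and 27 of 27 at 30 mg/m3 (7.1e-14; adjusted p = 0.415 with an estimated correlation). Over all genes 3 and 17 fell, and 14 and 22 fell when adjusted over the list alone, such as Cdk1 at -1.14 at 30 mg/m3. Collagen genes were lower in both (0.000216; adjusted p = 0.613 with an estimated correlation, and 0.000351; adjusted p = 0.707 with an estimated correlation), with 6 and 10 fallen adjusted over the list alone. Interferon response genes were lower too (0.00299; adjusted p = 0.994 with an estimated correlation, and 4.31e-07; adjusted p = 0.707 with an estimated correlation), with 1 and 14 fallen adjusted over the list alone, among them the antiviral gene Mx1 at -0.95 at 30 mg/m3. The exact permutation test called 5 lists at 30 mg/m3 and 0 at 10 mg/m3: proliferation genes, thymus markers and immediate early genes (adjusted p = 0.0274 each), mesothelial markers (0.0411) and interferon response genes (0.0494). By fry, 3 lists passed at 30 mg/m3 and 1 at 10 mg/m3, and with an estimated correlation 0 passed in either. In all, camera called 10 lists at 10 mg/m3 and 7 at 30 mg/m3. The lists were tested over time only after the data had been seen.

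Between day 1 and day 27 in air, 466 genes passed at 10 mg/m3, 326 higher and 140 lower, and 2007 at 30 mg/m3, 863 higher and 1144 lower. Both studies shared 86 genes that rose, where 18.3 were the number under chance, and 73 that fell, where 10.4 were. There was 1 gene that moved in opposite directions. Fisher's exact test of the overlap, taken without regard to direction, gave a one-sided p = 4.87e-33. It treats genes as independent replicates, which they are not, so that p is too small. Pearson's r across 15323 genes was 0.404. The share of mitochondrial ribosomal RNA was higher at day 27 too, 0.733 ± 1.28% and 3.34 ± 0.456% at 10 mg/m3 (SD, n = 5 and 4) and 0.459 ± 0.284% and 1.14 ± 0.433% at 30 mg/m3 (SD, n = 6 and 6), a difference that was not tested. With that share as a covariate, an alternative chosen after seeing the data, 5 genes passed at 10 mg/m3 and 185 at 30 mg/m3; with only the compared groups in the fit, 0 passed at 10 mg/m3. The count at 10 mg/m3 was 2 without air rat 18 of day 1 and 1467 without air rat 21 of day 1, and age, time and handling are confounded between the days.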

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

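Of the tests in this part, those on the order of the animals, on the dose and the clock, on the cardiac score, on the mitochondrial ribosomal RNA share and without the libraries with counts for over 21000 genes were chosen only after the result was seen. Each group of rats was tested for a library far from its neighbours on 15 measures, and 13 of 180 such tests singled out a library; chance alone singles out about 1 in 20 groups, or 9.

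Dust rat 27 of day 1 at 10 mg/m3 had the lowest total of its group, 3.42 M counts against 9.26 M for the nearest library, the fewest genes with a count (17873 against 19185), the highest mitochondrial ribosomal RNA share (2.62% against 0.819%) and the lowest log2 Sftpc level (12.8 against 13.3). Air rat 21 of day 1 at 10 mg/m3 had 3.01% mitochondrial ribosomal RNA against 0.314%, and air rat 17 of that group the lowest clock score (-1.89 against -1.36) and the lowest log2 Lcn2 level (4.59 against 6.16). Air rat 37 of day 7 at 10 mg/m3 had 4.43% mitochondrial ribosomal RNA against 1.48% and the highest cardiac score (5.98 against 1.8). For Alb, air rat 6 of day 27 at 10 mg/m3 was lowest at a log2 CPM of 4.5 against 5.73, and air rat 65 of day 7 at 30 mg/m3 highest at 8.53 against 5.05. For Ccl2, dust rat 59 of day 1 at 30 mg/m3 was lowest at 1.94 against 2.51, and air rat 69 of day 7 at 30 mg/m3 highest at 2.58 against 2.03. Between the doses, 1678 genes had dust effects that differed on day 1, among them Ogn-2 (3.95), Crp (2.88), Hsd17b13 (2.52), Ccdc183 (2.09), Gtf2a1l (1.93), Lpo (-4.24), Rag1 (-3.08), Pitx1 (-2.58), RT1-DMb (-2.30) and Dbp (-2.23).

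Clock genes changed with dust in the mean effect at 10 mg/m3, and a clock score was formed from Dbp, Tef, Per3 and Nr1d2 minus Arntl, Npas2 and Clock; Dbp, Tef, Nr1d2 and Arntl are 4 of the 5 genes called in that effect. Because the score holds genes picked at 10 mg/m3, a smaller effect at 30 mg/m3 is expected from the choice alone and settles nothing: its dust effect was smaller at 30 than at 10 mg/m3 by -0.89 (0.451 and 1.34; permutation p = 0.03, two-sided), but by -0.294 (permutation p = 0.4) once the slope on the number in the title, within groups, was taken off. The order in which rats were handled through the day is a candidate explanation: within groups of the same treatment and day the score rose with the number in the title, with a mean Spearman's rho of 0.785 (permutation p = 1e-05, the smallest that can be reached), between 0.5 and 0.943 in each of the 12 groups. Dust rats carried numbers higher by 10.8, 9.6 and 10.8 at 10 mg/m3, and the slope within groups predicts score differences of 2.37, 2.1 and 2.36 where 1.77, 0.78 and 1.47 were seen; at 30 mg/m3 it predicts 1.57, 1.64 and 1.83 where 0.374, 0.0258 and 0.954 were seen, so it predicts too much at both doses. That the number follows the hour of tissue collection is not stated in the labels, and a dust effect on the clock stays open.

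Cardiac genes fell with dust at 30 mg/m3 on day 7. A smaller share of heart muscle from the pulmonary veins in those tissue pieces is a candidate explanation: within the groups of days 1 and 27, the 10 called genes followed a score of other cardiac genes (Myh6, Myl7, Actc1, Tnnt2, Tnni3 and Mybpc3) with a median r of 0.689 (0.204 to 0.934), against 0.0226 over all genes tested. Myh6, an abundant transcript of that muscle, ran from 120 to 408 CPM in air and from 9.2 to 74.2 CPM in dust, but Alb, of liver, parted the groups as well (15.6 to 368 and 7.09 to 12.7 CPM), so the groups differed in more than cardiac transcripts. With the score as a covariate, the median log2 change of the 10 genes went from -1.49 to -0.839 and its median standard error from 0.27 to 0.243, so the calls ended because the change shrank; 0 of the 10 passed, as with the mitochondrial ribosomal RNA share as a covariate. A dust effect beyond the score cannot be told apart from an imperfect score, because every dust library of that day lay below every air library in Myh6.

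Genes whose dust effect differed between the doses on day 1 have a candidate technical explanation in the mitochondrial ribosomal RNA share, whose log2 difference of dust and air was 1.66 at 10 mg/m3 and -0.65 at 30 mg/m3, neither past the threshold (adjusted p = 0.286 for both), the first with an outlying library in each group (air rat 21 and dust rat 27). Across the 1678 genes, the slope on this share within groups of days 7 and 27 went with the day 1 difference at r = -0.691 (permutation p = 0.037, two-sided, 1000 permutations; genes are not independent replicates). With the share as a covariate 92 of the 1678 passed, and the median size of the difference went from 0.587 to 0.404 with a median standard error of 0.166 and 0.163, so the calls ended because the differences shrank. The air libraries with counts for over 21000 genes are argued against as the cause, since 3115 genes passed without them, 1617 of them shared. The dose itself stays open as a biological explanation, because dose and study are confounded.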

How the results depend on the processing

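The tests with the cardiac score, the mitochondrial ribosomal RNA share, without the libraries above 100 CPM of Alb and without those with counts for over 21000 genes were chosen only after the result was seen. Of 3616 values of named genes under alternatives, 47 had the opposite direction to the reported value; they belong to 17 of the 138 reported values, none of which had passed, and such values include Hmox1 and Mmp12 at 10 mg/m3 on day 7 without air rat 36 and Spp1 at 30 mg/m3 on day 1 without air rat 52. Of the 66 values past the threshold 0 turned; 57 kept their call with median-of-ratios factors, 54 with DESeq2, 56 with limma voom, 40 without a filter, 62 with a stricter filter, 20 of the 48 tested with only the compared groups, 8 with the mitochondrial ribosomal RNA share and 16 under every omission of a single library. Counts of genes are given for dust against air unless stated, as reported and then under the alternative, and the cause was not tested except where given. At 10 mg/m3 on day 1, 20 became 11 with median-of-ratios factors (5 higher, 6 lower), 5 without a filter, 8 without robust estimation, 473 with DESeq2, 520 with limma voom, 35 with a surrogate variable, 3 with only the compared groups, 6 without libraries high in Alb and 0 with the mitochondrial ribosomal RNA share; on day 27, 0 became 1 with only the compared groups. At 30 mg/m3 on day 1, 0 became 37 with DESeq2, 1 with the cardiac score and 877 without the libraries with over 21000 genes. At 30 mg/m3 on day 7, 10 became 6 without a filter, 18 without robust estimation, 55 with DESeq2, 21 with limma voom, 5 with a surrogate variable, 36 with only the compared groups, 0 with the cardiac score, 29 without libraries high in Alb and 0 with the mitochondrial ribosomal RNA share; on day 27, 0 became 45 with limma voom. For the mean effect at 10 mg/m3, 5 became 21 with DESeq2, 36 with limma voom, 2 with a surrogate variable, 2 with the cardiac score, 2 without libraries high in Alb and 3 with the mitochondrial ribosomal RNA share. For the mean effect at 30 mg/m3, 187 became 107 without a filter, 417 with DESeq2, 1047 with limma voom, 107 with a surrogate variable, 34 with the cardiac score, 0 without libraries high in Alb, 1014 without the libraries with over 21000 genes, 1 with the mitochondrial ribosomal RNA share, and 20 with a fold of at least 1.5, which only removes genes. For the dependence on the day, 0 became 1 with limma voom at 10 mg/m3, and at 30 mg/m3 46 with DESeq2 and 3 without the libraries with over 21000 genes. For the dose difference on day 1, 1678 became 978 without a filter, 6 with only the compared groups, 848 without the library that stands apart, 847 with a fold of at least 1.5, 3115 without the libraries with over 21000 genes and 97 with the mitochondrial ribosomal RNA share; on day 7, 0 became 14 with DESeq2, 213 with limma voom, 34 with a surrogate variable and 2 with only the compared groups. For air over time at 10 mg/m3, 466 became 268 without a filter, 945 with DESeq2, 1881 with limma voom, 0 with only the compared groups, 905 without the library that stands apart, 197 with a fold of at least 1.5 and 5 with the mitochondrial ribosomal RNA share; at 30 mg/m3, 2007 became 3700 with limma voom, 455 with a fold of at least 1.5, 1052 without the libraries with over 21000 genes and 185 with the mitochondrial ribosomal RNA share. Under the stricter filter every count of genes stayed within 1.5 times the reported one. No gene was called at both doses in the same direction under any alternative fixed before the data were examined. Calls at both doses in opposite directions were not counted. Camera called 3, 9 and 14 lists at 10 mg/m3 and 8, 10 and 11 at 30 mg/m3. Of these, 0 were left with an estimated correlation and 0 by fry, except 1 on day 7 at 30 mg/m3 by both. The exact permutation test called 0 on every day. Its smallest possible p is 0.00794 for 5 against 5 rats, 0.0286 for 4 against 4 and 0.00216 for 6 against 6, so 1 list alone cannot pass over 38 lists. With 6 against 6 rats several lists can pass together, as 5 did for air over time at 30 mg/m3. The counts of 0 at 30 mg/m3 thus give the camera calls there no backing. On day 7 the cardiac list reached the smallest possible p of 0.00216 in this permutation test. Its failure to pass after adjustment therefore does not speak against its call. At 10 mg/m3 the smallest possible p is higher, and the counts of 0 there say little about stability. Leaving out 1 library gave 1 to 1147 genes at 10 mg/m3 on day 1 (1 without air rat 17 or dust rats 29 or 31, 2 without air rat 19 or dust rat 32, 3 without air rat 18, 5 without air rat 20, 7 without dust rat 30, 1147 without air rat 21), 0 to 220 at 30 mg/m3 on day 1 (220 without air rat 53, 1 without dust rats 57 or 59) and 0 to 21 at 30 mg/m3 on day 7 (0 without air rat 70 or dust rats 76 or 79, 3 without air rat 71 or dust rat 74, 4 without air rat 68 or dust rats 73 or 77, 20 without air rat 65, 21 without air rat 66). It gave 2 to 20 for the mean effect at 10 mg/m3 (2 without air rats 17, 33, 1 or 3 or dust rats 31, 48, 15 or 16, 3 without air rats 18 or 34, 8 without air rat 6 or dust rat 43, 9 without air rat 39, 20 without air rat 21) and 22 to 610 for that at 30 mg/m3, where 25 of 36 omissions moved it (90, 610, 82, 64 without air rats 49, 53, 54, 55; 76, 98, 63 without dust rats 60, 61, 62; 64, 100, 441, 71 without air rats 65, 66, 69, 71; 82, 107, 82, 22 without dust rats 74, 76, 77, 79; 86, 69, 101, 115 without air rats 81, 82, 85, 87; 283, 103, 296, 57, 123, 25 without dust rats 89, 90, 91, 92, 94, 96). It gave 0 to 57 for the dependence on the day at 10 mg/m3 (57 without air rat 6, 11 without air rat 21) and 452 to 2825 for the dose difference on day 1 (452 without air rat 17, 679, 720 and 2825 without air rats 54, 55 and 53, 848, 970 and 1053 without dust rats 27, 61 and 62, 2616 without air rat 21). It gave 0 to 67 on day 7 (67 without air rat 37, 6 without air rat 68) and 0 to 1 on day 27 (1 without air rats 3, 5 or 6). For air over time it gave 2 to 1467 at 10 mg/m3 (2, 99, 261 and 1467 without rats 18, 19, 20 and 21 of day 1, 133, 153 and 58 without rats 1, 3 and 5 of day 27) and 1068 to 2778 at 30 mg/m3 (1068 and 1226 without rats 52 and 53 of day 1, 1330 and 1303 without rats 81 and 85 of day 27). Lists called by camera ranged from 3 to 11 (dust rat 27), 6 to 17 (air rat 36, dust rat 47) and 8 (air rat 3) to 18 at 10 mg/m3, and from 4 (dust rat 58) to 13 (air rat 49, dust rat 62), 4 (dust rat 79) to 11 and 7 (air rats 81 and 84) to 14 at 30 mg/m3. On simulated data with the real library sizes, over the 6 dust comparisons, 1.5-fold changes were recovered in 47.8% to 76.1% of cases, 2-fold changes in 73.1% to 82.1% and 4-fold changes in 93.9% to 100%. Genes were drawn independently there, so a structure shared among libraries was left out of these rates.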

Other observations

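Transcripts best known from liver were present in all groups; the relation between them was tested only after the data were seen. Alb had a median of 38.2 CPM, and 6 libraries exceeded 100 CPM: air rat 33 of day 7 at 10 mg/m3 with 135 CPM, and in the 30 mg/m3 study dust rats 59 (127) and 62 (164) of day 1, air rat 65 of day 7 (368) and dust rats 91 (151) and 96 (252) of day 27. Over 64 libraries log2 Alb and log2 Apob, the genes of albumin and of the main lipoprotein of liver, were related with Pearson's r of 0.971 and Spearman's rho of 0.96 (permutation p = 1e-05 for both, the smallest that can be reached), with r of 0.963 without the 2 farthest libraries and of 0.945 and 0.976 within the studies. This was the only relation of its kind that was computed across all libraries.

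Air rats 51 and 53 of day 1 at 30 mg/m3 had counts for 21889 and 22077 genes, where the other 62 libraries had between 17873 and 19731. In both of these and in no other library, 397 genes had a count, with 1429 counts in total. Whether genomic DNA or another library was mixed in was not tested, so the air values of day 1 at 30 mg/m3 are uncertain. LOC102553715 had 129.2 CPM in air rat 1 of day 27 at 10 mg/m3. The mitochondrial ribosomal RNA share in air of the 10 mg/m3 study was 0.733 ± 1.28% (SD, n = 5) at day 1, 1.61 ± 1.62% (SD, n = 5) at day 7 and 3.34 ± 0.456% (SD, n = 4) at day 27; these values were not tested against each other.

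Other splits of the same libraries, tests chosen before the results were seen, ask whether chance can be excluded for each count; those between 2 groups, and those for dose differences with their 4 groups, used a fit of these groups alone, so their counts differ from the reported ones. For dust at 10 mg/m3 on day 1, only the real split of 100 had as many as the 3 genes of the fit of these groups alone. The highest other had 2, so chance is only weakly argued against for these 3 genes. Of these 3 genes, 2 are among the reported 20, and the reported 20 were not tested in this way. Chance is argued against for the mean effect at 30 mg/m3 (1 of 50, 187 genes, highest other 1). The same holds for air over time at 30 mg/m3 (1 of 100, 1598 genes, highest other 219). With the real split always counted, 1 is the lowest number possible, and no adjustment was made over the results tested. By the count past the threshold alone, chance is weakly argued against for the mean effect at 10 mg/m3. There, 1 of 50 splits was as large (5 genes, highest other 0). For dust at 30 mg/m3 on day 7 it was 2 of 100 splits, the real one included (36 genes, highest other 538). For the dose difference of day 1, 2 of 50 splits, the real one included, had as many as the 6 genes of that smaller fit (highest other 6). A relabelled split reached the same count, so chance is only weakly argued against for these 6 genes. The reported 1678 were not tested in this way. For that of day 7, 2 of 50 splits had as many as the 2 genes of the smaller fit (highest other 6), but the reported fit called 0, so no result there is set apart from chance. It cannot be excluded for dust at 10 mg/m3 on day 7 (100 of 100; 0 genes, highest other 357) and day 27 (4 of 35; 1 gene, highest other 5), or for dust at 30 mg/m3 on day 1 (100 of 100; 0 genes, highest other 489) and day 27 (100 of 100; 0 genes, highest other 8). Nor can it for the dependence on the day (50 of 50 at both doses; 0 genes, highest other 7 and 158), the dose difference of day 27 (50 of 50; 0 genes, highest other 722) and air over time at 10 mg/m3 (100 of 100; 0 genes, highest other 883). A second measure of the same splits is the number of genes at an unadjusted p under 0.05. By it, chance cannot be excluded for 3 results where few splits were as large by the count past the threshold. These are dust at 30 mg/m3 on day 7 (16 of 100 as large, 984 genes, highest other 3969), the mean effect at 10 mg/m3 (4 of 50, 1453 genes, highest other 2099) and the dose difference of day 7 in the smaller fit (6 of 50, 1824 genes, highest other 4158). Splits that called many more genes than the real one, such as the highest other of 538 for dust at 30 mg/m3 on day 7 and those of 357, 489, 158, 722 and 883, point to a structure of the samples that the groups do not describe.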
